A study of Arabidopsis thaliana and Lactuca sativa with 158 samples.

How the data were processed

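The libraries were made from TRIzol-extracted total RNA of inflorescences and leaves (4 weeks old): per the labels, an adapter was ligated to the 3' ends, cDNA was made by template switching, barcoded, pooled and enriched with biotinylated probes, and read by nanopore sequencing. The authors demultiplexed the pooled reads with a custom pipeline and name the build TAIR10 and the trimming tool cutadapt without versions. For each library they deposited tables of normalised counts per target, of all reads for each library, of full-length reads collapsed by molecular identifier for each Arabidopsis library, and of full-length reads and of all reads collapsed by molecular identifier for the 10 inflorescence libraries. The values of these deposited tables have the unit signal: read counts divided by a factor that is not stated. Per the file headers the columns split the signal by strand and by reads marked pA or not, and shares computed from them here, on the authors' deposited values, are in percent. The worth of 1 read was inferred per library, after the tables were seen, as the largest unit of which the low values by strand and pA are whole multiples within their rounding, with the smallest value at 1 to 12 units. It was found in 158 of 158 libraries (3874 values, all whole by this choice, 3 to 28 values per library in lettuce), and was the smallest value itself in 150. The other 8 are lettuce libraries, where the smallest value is up to 10.0 units. The tables of a library share that unit, so they were scaled together and not each on its own. Its median was 0.913 in inflorescence, 1.28 in leaf and 4.77 in lettuce (3.59 to 6.98). The rounded unit is too coarse to turn high values into whole reads, so count-model alternatives were not run and no counting intervals are given. No 2 of the 158 libraries had identical tables (12403 pairs).

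Of the 86 targets 49 carry a gene identifier, and all 49 were found in the reference gene table, from which symbols were taken. Target classes are those in the deposited target names. Groups follow the labels. For 9 lettuce 35S libraries the replicate number in the table name differs from that in the sample title; the titles were used, and libraries are named after them. Both give the same pairs of fully green and fully red libraries. The lettuce libraries under Arabidopsis and lettuce ubiquitin promoters were pooled as ubiquitin promoter because labels and files name different promoters for some lines. The inflorescence samples are labelled as carrying RUBY, but their tables have no RUBY target, so no RUBY value was had for them.

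Comparisons between 2 groups used limma 3.58.1 in R 4.3.3 on log2(signal + 1), fitting only the libraries of these groups, with empirical Bayes moderation and a trend on the mean. A target was tested when it was above 0 in at least as many libraries as the smaller group holds, and called at a Benjamini-Hochberg adjusted p below 0.05. The trend was left out where fewer than 10 targets were tested (lettuce). The tables of reads collapsed by molecular identifier were used for inflorescence and those of all reads for leaf and lettuce. Overlapping targets share reads. RUBY was also tested with two-sided permutation tests of the difference of means (Python 3.11.15, numpy 2.4.6), by full enumeration or, where both groups held at least 10 libraries, by 100000 resamples with seed 1; p-values were adjusted over the 14 comparisons of RUBY or the 10 of the full-length ratio. The full-length ratio is log2(signal of full-length collapsed reads + 1) minus log2(signal of all reads + 1), both of RUBY; as the first is not above 0 in some leaf libraries of most groups, it depends on the pseudocount. The pA share of sense reads and the log2 changes of reads marked pA and not marked pA were added after the tables were seen and adjusted over 14 comparisons each.

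The targets named in the text follow a rule set beforehand: RUBY and other construct targets, then up to 10 called targets with the largest changes in each direction, then up to 4 further called members of each gene list or, with none called, the member with the highest mean, and genes mutated in the mutant lines where they are targets (DCL4 and AT2G40030). Further called targets and the targets of fits with the numbering set as a term were chosen after their values were seen. Gene lists were tested as sets with limma's camera (preset correlation 0.01, at least 5 tested members, 24 tests) and with an estimated correlation. The list of transposable elements was matched by element identifiers and family names only, so elements known by a gene identifier are not members. The lists for silencing machinery (up to 8 tested members), tasiRNA precursors (1, so that its adjusted p over the list is the unadjusted p), transposable elements (up to 25) and transgenes (up to 5) had tested members; over all 16 comparisons 4 transgene calls were rises and 7 falls (13 adjusted over the list alone), and 14 calls of transposable elements were rises and 11 falls (25 adjusted over the list alone). The lists for DNA methylation and chromatin, RNA decay, methylation-silenced genes, control genes, senescence and stress, photosynthetic leaf cells and flowers had 0 tested members, so the probes give no marker of other cell types.

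Libraries of 35S leaves in Col-0 fall into 2 numbering sets by the prefixes of their table names. This grouping is an inference, made after the tables were seen. Comparisons were repeated within each set, with the set as a term and, for dcl1234, against the reference libraries of each set. The alternatives set in advance were pseudocounts of 0.1 and 10, no filter, libraries centred on their median over tested targets other than the transgene, limma without trend and with robust moderation, the other read tables, replicate or plant numbers as a block, 1 value per line, and leaving out each library of groups of 2 to 5. Simulated changes were tested on resampled data: with 10 changed targets and 20 repeats, log2 changes of 1, 2 and 4 were recovered in 0.5, 21.5 and 83% of cases for ddm1 against Col-0 and in 33, 73.5 and 96% for 35S green against red parts, with at most 1.56% false calls in any comparison. Figures were drawn with matplotlib 3.10.9.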

Results

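RNA from chosen loci was captured with probes and read as long cDNA on a nanopore sequencer in 158 libraries, 122 from Arabidopsis thaliana (Columbia) and 36 from lettuce (Salinas). The tables hold 86 targets, among them transposable elements, loci of RNA-directed DNA methylation (RdDM), sources of small RNAs, protein-coding genes, elements of transgene constructs and RUBY, a reporter whose enzymes make red betalain pigment. Inflorescences came from Col-0 (n = 3), ddm1 (n = 3), polv (n = 3) and a double mutant poliv polv (n = 1). Leaves with RUBY under the 35S promoter were named by colour on the labels as red parts (n = 13), green parts (n = 13), fully red (n = 13), fully green (n = 9), always red (n = 11) and always green (n = 2), with 8 always red leaves of the dcl1234 mutant. Leaves with the maize ubiquitin promoter (ZmUBQ) were fully red (n = 9), fully green (n = 9) or always red (n = 4). The construct RUBY_3Q gave 3 always red, 3 always green, 2 fully red and 2 fully green leaves, and RUBY_fs gave 6 always green leaves; the labels do not say what sets these constructs apart. Lettuce leaves held RUBY under the 35S promoter (n = 3 for each of always red, always green, fully red and fully green) or under a ubiquitin promoter (6 always red, 6 always green, 4 red parts, 4 green parts, 2 fully red and 2 fully green). The summed signal of all reads had a median of 758504 in leaf (310094 to 986258), of 1115740.0 in inflorescence and of 4940 in lettuce (292 to 130614). Divided by the worth of 1 read, inferred for each library from its low values, this sum had a median of 596939 in leaf. In lettuce that median was 832 (50.0 to 31626), so low lettuce values rest on few reads. The inflorescence tests used reads collapsed by molecular identifier, whose summed signal was far lower, at 53123.5 to 87242 per library. The p-values measure only the spread between these samples, several of which come from the same transgenic line.

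In ddm1 inflorescences, which lack the chromatin remodeller that keeps transposable elements methylated, 17 of the 19 tested targets of the methylated transposable element class were higher than in Col-0. AT4TE20070 had the largest rise, to a signal of 1692 ± 953 from 2.91 ± 3.67 (SD, n = 3 and 3), a log2 fold change of 9.11 (SE 0.90). AT2G02205 rose to 2920.3 ± 107 from 5.34 ± 1.49, a log2 fold change of 8.87. AT4TE20065 (8.85), AT4TE20095 (7.93), AT4G07965 (7.89) and AT4TE20080 (6.53) of the same group of chromosome 4 elements rose as well, as did AT3G44215 (6.78), AT5G17125 (5.57) and AT2G02210 (5.45). The element AtMu1 of the Mutator family rose in 3 of its targets, AT4TE23190 (7.07), AT4TE23195 (4.44) and AT4TE23200 (4.24), and AT4TE20085 rose by a log2 of 4.22. The 2 tested members that did not pass were AT4TE23185 of AtMu1, which was lower (-1.79), and AT4TE20090 (1.56). The smallest rise that passed was that of AT2G02190, to 272 ± 39.0 from 40.7 ± 41.9 (log2 fold change 3.16). No target of the RdDM class (10 tested), the phased small RNA class (11), the unmethylated transposable element class (5), the protein-coding class (15) or the construct class (5) passed. AGO1, the main slicer of microRNA silencing, had a log2 fold change of 0.82 (limma adjusted p = 0.44), DCL4 of 0.24, and the tasiRNA precursor TAS3 of 0.09. The construct target with the highest mean, GUS, had a signal of 37055 in Col-0 replicate 2 alone and did not pass (log2 fold change -1.59). Construct targets made up 63.1% of the summed signal of that library. Its protein-coding sum was 14464, against 37515 and 38191 in the other Col-0 libraries, which lowers the Col-0 means that small changes such as that of AGO1 are set against.

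By limma, 17 of 65 targets passed at an adjusted p below 0.05 (17 at an unadjusted p below 0.05), all higher in ddm1, with adjusted p = 9.57e-09 for AT2G02205 and 0.00451 for AT2G02190. In all 17 the groups did not overlap, which a call at 3 against 3 nearly requires, so it adds no support. Over all tested targets the groups were apart in 17 of 19 of the methylated and 4 of 15 of the protein-coding class. In the other classes 0 were apart, where chance gives 10% of unselected targets for 3 against 3. The median change over targets other than the transgene was 0.48. Centring each library on its median took 1.94 from every log2 change, more than that, as the rises themselves raise the median. So centred, the same 17 targets rose and 34 fell, of which 22 had been higher in ddm1 before, such as AGO1 (0.82 before, -1.12 after), so these falls rest largely on that subtraction. Of the fixed list of transposable elements, 8 of 25 tested members rose (8 adjusted over the list alone), and the list as a set did not pass (limma's camera, adjusted p = 0.847). That test sets the list against the other targets, which hold risen elements known by a gene identifier, such as AT2G02205 and AT2G02210. It therefore cannot decide whether the elements changed as a set.

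**Figure D1:**
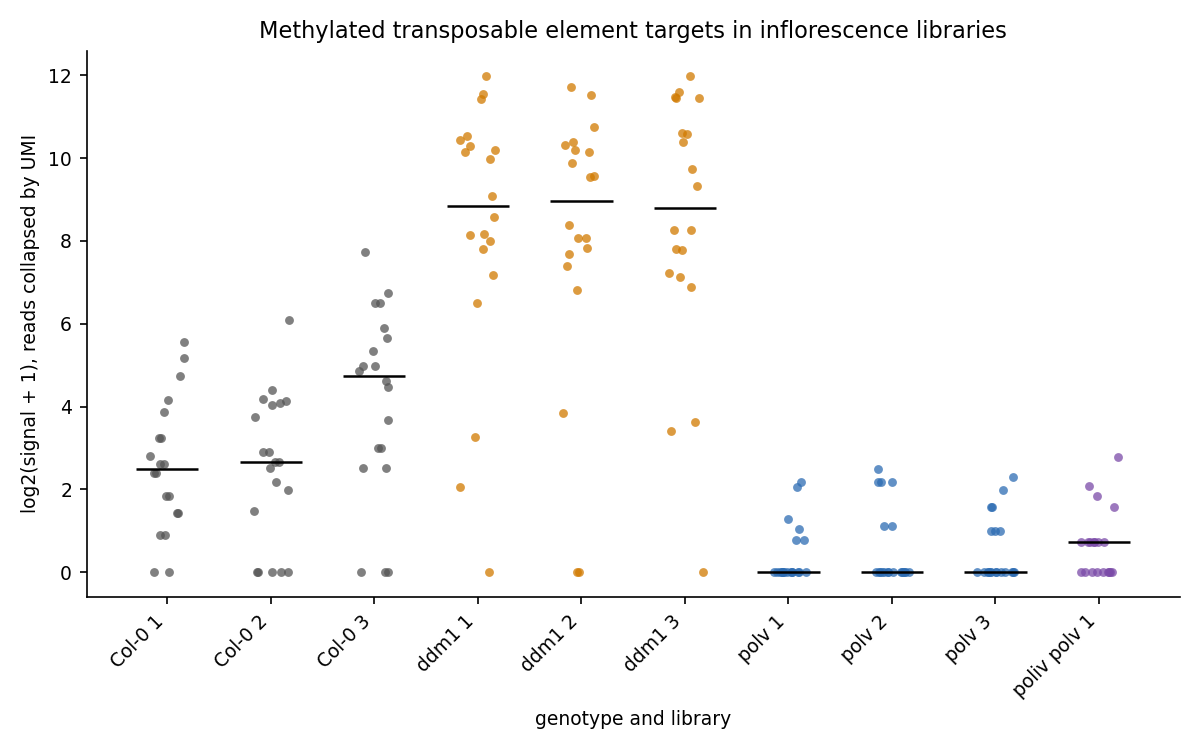
Signal of methylated transposable element targets, as log2(signal + 1) of reads collapsed by molecular identifier, in each inflorescence library, with a point per target and a bar at the median. Of the 20 targets 18 have a higher mean in ddm1 than in Col-0 and 19 a lower one in polv, as AT2G02210 does with means of 3844, 108 and 2.14 in ddm1, Col-0 and polv. AT4TE23185 is lower in ddm1 (4.26 against 15.8), AT4TE20090 lies below Col-0 replicate 3 in each ddm1 library, and AT4TE20055 is at 0 in all libraries.

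In polv inflorescences, which lack the polymerase that makes the scaffold RNA of RdDM, 11 of 14 tested methylated transposable element targets were lower than in Col-0, with a class median log2 change of -3.31. AT2G02210 fell to a signal of 2.14 ± 1.87 from 108 ± 89.8 (SD, n = 3 and 3), a log2 fold change of -5.08 (SE 0.81, limma adjusted p = 6.33e-05). AT2G02190 (-4.59), AT4G07967 (-4.32), AT5G17125 (-3.69) and AT2G02200 (-3.15) fell too, as did AtMu1 in AT4TE23195 (-3.12) and AT4TE23200 (-2.73). AT4G07970, AT4TE23185, AT4TE20085 and AT4G07965 were listed at 0 in all 3 polv libraries, against means of 26.2, 15.8, 14.2 and 12.2 in Col-0. These means rest on few reads. AT4G07965 was at 0.850, 5.33 and 30.5 in Col-0 replicates 1, 2 and 3, where 1 read was worth 0.850, 0.592 and 2.34. Outside that class, the unmethylated element AT5TE76205 fell (-4.95), while its neighbours AT5G52070 (1.14), AT5TE76210 (1.42) and AT5TE76215 (1.44) were higher and passed with centring alone. Of 10 RdDM loci 1 fell, AT3TE70480, to 8.68 ± 1.53 from 64.6 ± 33.4 (-2.66). The construct elements NosTerm (23792 ± 6451 from 110.0 ± 187, log2 fold change 10.66), 35SPro (7.86) and NosPro (4.59), parts common in T-DNA vectors, rose. AGO1 (-0.37), TAS3 (-0.57) and DCL4 (-0.11) did not pass.

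By limma, 16 of 59 targets passed, 3 higher and 13 lower in polv (19 at an unadjusted p below 0.05). The median of the other targets was shifted by -0.50; with centring 6 rose and 12 fell, 15 of them shared, and AT4G07965 no longer passed (adjusted p = 0.109). The 3 targets that centring added are AT5G52070 (1.53), AT5TE76210 (1.81) and AT5TE76215 (1.83). Without Col-0 replicate 2, the library with the high GUS signal, 43 targets passed. On the tables of full-length reads 2 targets passed. Of the list of transposable elements 6 of 19 tested members fell (6 adjusted over the list alone), and the list as a set did not pass (camera, adjusted p = 0.767). Here too the other targets hold fallen elements known by a gene identifier, such as AT2G02210, so the set test cannot decide.

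Green and red parts of 35S leaves were compared for the RNA that goes with the loss of pigment. RUBY was lower in green parts, at a signal of 119855 ± 32672 against 297773 ± 67226 in red parts (SD, n = 13 and 13), a log2 fold change of -1.33, and each green library lay below each red one. The fall was larger among reads marked pA, taken here as polyadenylated (log2 fold change -2.31), than among the others (-0.32, which did not pass), so that the pA share of RUBY's sense reads was 37.2% ± 13.3 in green and 68.7% ± 8.25 in red parts. Full-length RUBY reads, collapsed by molecular identifier, were few, with a signal of 13.8 ± 11.7 in green and 161 ± 142 in red parts, and the full-length ratio, their log2 over all RUBY reads, differed by -2.01. No other target passed: AGO1 (0.29), TAS3 (0.57), DCL4 (0.41), GUS (1.51) and the Pol V subunit gene AT2G40030 (0.04) had changes within the spread of the libraries.

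The two-sided permutation p for RUBY was 1e-05, the smallest that 100000 resamples can give (adjusted p = 7e-05 over 14 comparisons), and limma gave a SE of 0.21 and an adjusted p = 1.99e-05, with RUBY alone passing of 57 targets (2 at an unadjusted p below 0.05). The pA share had adjusted permutation p = 6.17e-05, and the full-length ratio adjusted permutation p = 0.0453. The other targets' median was shifted by 0.30 (RUBY -1.68 when centred). The number prefixes of the libraries form 2 sets, and 40 of 57 targets differed between them by limma with colour as a term. RUBY changed by -1.08 within the first set (4 against 4, exact permutation p = 0.0286, the smallest possible) and by -1.44 within the second (9 against 9, exact permutation p = 4.11e-05). The pA share differed by -37.0 and -29.0 points, and the full-length ratio by -3.98 and by -1.13, which did not pass within either set after adjustment. The ratio also lost its call with a pseudocount of 10 (-1.06) and with line means (-1.99).

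**Figure D2:**
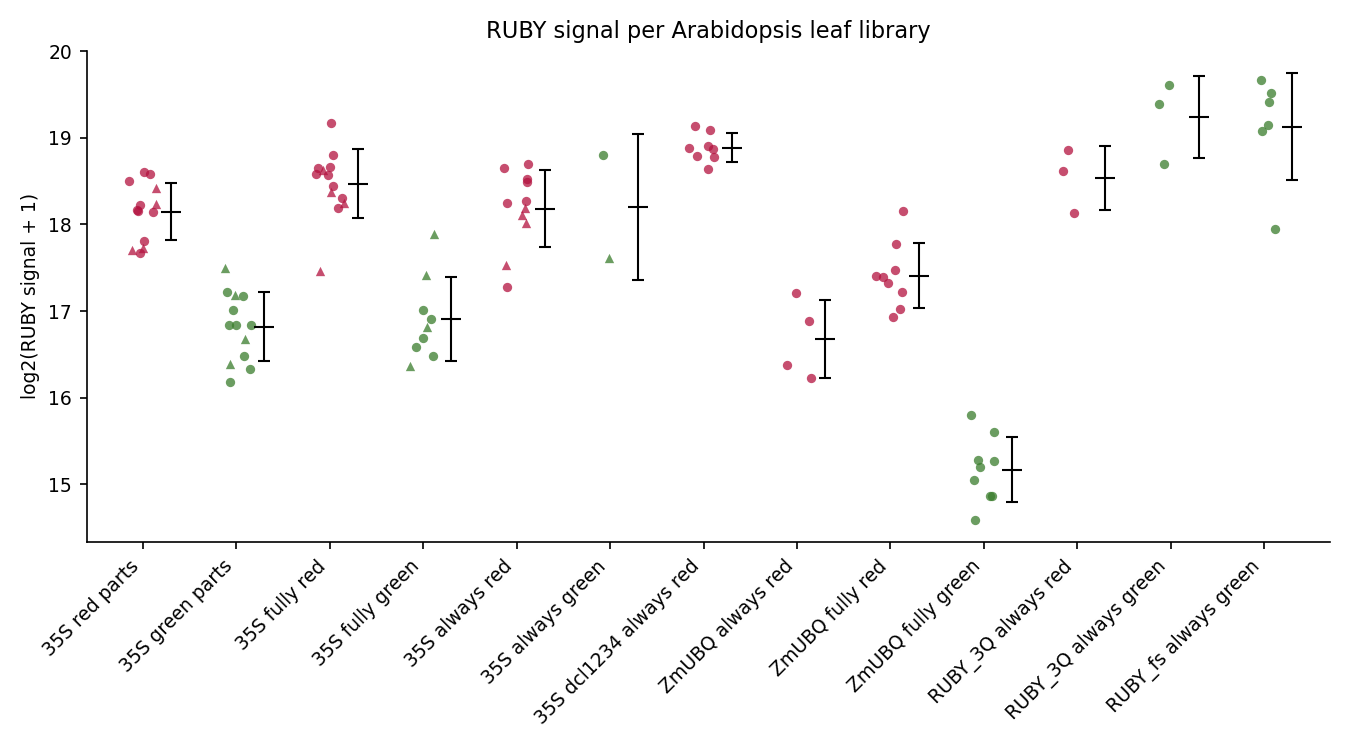
RUBY as log2(signal + 1) in each leaf library by construct and colour, with triangles for libraries of the first numbering set, circles for the others and a black bar for the mean ± SD. Green parts average 16.82 and red parts 18.15, while always green leaves with RUBY_fs average 19.13.

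Whole leaves of the 35S plants gave the same comparison. RUBY was lower in fully green than in fully red leaves, at 129605 ± 50303 against 374847 ± 95768 (SD, n = 9 and 13), a log2 fold change of -1.56. Reads marked pA fell by 2.70 on the log2 scale, and the others changed by -0.33, which did not pass. The pA share was 34.1% ± 9.83 in fully green and 71.8% ± 5.82 in fully red leaves, with no overlap. AGO1 (0.08), DCL4 (0.52), TAS3 (0.77), GUS (0.89) and AT2G40030 (0.47) did not pass.

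The exact permutation test of RUBY gave a two-sided p = 4.02e-06 (adjusted p = 5.63e-05), that of the pA share p = 2.01e-06, the smallest possible (adjusted p = 2.81e-05), and that of the full-length ratio (-2.50) an adjusted p = 0.0769. By limma RUBY alone passed of 60 targets (SE 0.29, adjusted p = 0.000207; 2 at an unadjusted p below 0.05), with a shift of the others of 0.29 and a centred RUBY change of -2.01. Within the first numbering set RUBY changed by -1.06 (4 against 4, exact permutation p = 0.0571) and within the second by -1.86 (5 against 9, exact permutation p = 0.0005), and the pA share by -42.9 and -32.4 points. With the set as a term in limma, 7 targets passed: RUBY and, higher in green, HST (AT3G11945, 1.33), AT3G12210 (1.02), AGO4 (0.89), AXS2 (0.82), DCL4 (0.75) and AT1G63080 (0.71). Centring without that term left HST at 0.60, AT3G12210 at 0.31, AXS2 at 0.18, AGO4 at 0.14, DCL4 at 0.08 and AT1G63080 at 0.05. None of these passed, so the rises are not told apart from the shift of the libraries.

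Fully red and always red leaves of the 35S plants, both red on the labels, were compared as well. RUBY signal was 374847 ± 95768 in fully red and 309676 ± 84842 in always red leaves (SD, n = 13 and 11), a log2 difference of 0.29 that did not pass. Reads of RUBY not marked pA rose by 0.53 on the log2 scale, and the pA share was lower by 4.60 points (difference -4.60), at 71.8% ± 5.82 against 76.4% ± 3.18. TAS3 had a change of -1.03, AGO1 of -0.09, AT2G40030 of -0.59, DCL4 of -0.25, AT5TE63500 of -0.42 and GUS of -0.73, none of which passed over all targets (TAS3 unadjusted limma p = 0.0077).

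By permutation test RUBY had an adjusted p = 0.16, its reads not marked pA 0.0299 and the pA share 0.0468. The pA share differed by -7.88 points within the first set and by -3.14 within the second, neither of which passed, nor did the difference beyond that of the other targets (-3.40 points). By limma 0 of 58 targets passed (3 at an unadjusted p below 0.05), and the other targets were shifted by -0.28; centring brought 1 call. RUBY differed by 0.22 and 0.29 within the sets.

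In 2 always green leaves of the 35S plants RUBY had a signal of 327882 ± 180816, against 309676 ± 84842 in always red leaves (SD, n = 2 and 11), a log2 difference of 0.02 (SE 0.44) that did not pass. Both green leaves are of line MK017 and no always red leaf is, so colour cannot be told apart from line in this comparison. Of the RUBY sense reads of the green leaves 36.7% ± 9.50 were marked pA, against 76.4% ± 3.18, and reads not marked pA rose by 1.43 on the log2 scale. AGO4, the slicer of RdDM, fell by 1.60 on the log2 scale (1142 ± 375 against 3513 ± 1056), and PDS1, an enzyme of plastoquinone and tocopherol synthesis, fell by 1.74. AT3TE19440, an element listed under the GRF5 locus, was at 19.9 ± 20.3 against 0.193 ± 0.639 (3.77), with about 1 read in 1 of the 2 leaves (MK017_2) and 71 in the other. GRF5, with the same values in the green leaves but 2.54 ± 5.75 in always red leaves, did not pass (3.22, limma adjusted p = 0.121). Without MK017_1, which leaves 1 green leaf, the change of the element was 2.56. AGO1 (-0.76), TAS3 (-0.83), DCL4 (-0.83) and AT2G40030 (-1.61) did not pass, and neither did eGFP (8.07), which had a signal of 242115 in 1 of the 2 leaves.

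By exact permutation test the pA share had p = 0.0128, the smallest possible (adjusted p = 0.0299), and so had the reads not marked pA. By limma 3 of 72 targets passed, 1 higher and 2 lower (18 at an unadjusted p below 0.05); as the other targets were shifted by -1.01, centring left 1 higher and 0 lower, with AGO4 at -0.50 and PDS1 at -0.64. Each numbering set holds 1 of the 2 green leaves, so no value within sets was had. With the set as a term 28 targets passed, 3 higher and 25 lower, among the latter AGO6 (-4.68), AGO4 (-1.50), AT2G40030 (-1.43), SDE3 (-1.27), RDR6 (-1.06), TAS3 (-0.86) and AGO1 (-0.58), where the median of the other targets was -0.87. With the set as a term and centring 0 were lower and 2 higher, AT3TE19440 (4.66) and eGFP (8.39), so the falls are not told apart from the shift of the libraries. With the green leaf with eGFP (MK017_1) as the 1 green leaf, so without MK017_2, RUBY turned to -0.57. Among full-length reads RUBY differed by -3.63. In the silencing machinery list (8 tested) AGO4 alone fell without that term, with 2 members passing adjusted over the list alone.

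The dcl1234 mutant, with lesions in the Dicer-like enzymes that make small RNAs, was compared with Col-0 in always red 35S leaves. RUBY was higher in the mutant, at 487287 ± 56379 against 309676 ± 84842 (SD, n = 8 and 11), a log2 fold change of 0.70. The rise lay among reads not marked pA (1.59), while reads marked pA changed by 0.27, which did not pass, and the pA share was 56.6% ± 3.34 against 76.4% ± 3.18 with no overlap. Full-length RUBY reads had a signal of 1255 ± 785 in the mutant and 52.9 ± 68.2 in Col-0, and the full-length ratio was higher by 4.68 on the log2 scale. GRF5, a growth regulator, rose from 2.54 ± 5.75 to 309 ± 279.7 (6.52). Targets with element identifiers went both ways. AtMu1 in AT4TE23200 (5.40), AT5TE76220 (4.40), AT5TE76215 (2.10, 10638 ± 2161 against 2804 ± 1564), AT5TE76210 (2.06) and AT5TE28750 rose. AT5TE76200 (-5.57), AT5TE76205 (-5.36), AT5TE35520 (-2.92), AT5TE63505 (-1.54) and AT5TE63500 (-1.51) fell. By class AT5TE28750 and AT5TE35520 are protein-coding targets, listed under SGS3 and ALY1. AT5TE63505 and AT5TE63500 are phased small RNA targets, listed under AT5G43740. SADHU1-1 (1.80), AT5G52070 (1.48), LBD41 (1.49) and the overlapping genes AT1G06000 and AT1G06002 (both 1.83, with mirrored reads) rose too. AT4G07967 (-3.02), AT2G02210 (-2.27), the disease resistance gene homologue AT5G43740 (-1.40), the flowering gene AGL20 (-1.38), AT1G62920 (-0.78) and PDS1 (-0.77) fell. AGO4 rose by 0.61, and AGO1 (0.13), TAS3 (-0.46), DCL4 (0.48), AT2G40030 (0.00) and GUS (-1.79) did not pass; the DCL4 target does not test the mutation.

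By limma 29 of 60 targets passed, 18 higher and 11 lower (33 at an unadjusted p below 0.05); the other targets were shifted by 0.30, and with centring 12 rose and 13 fell, 23 of them shared. Centring ended the calls of AGO4, SUR1, AXS2, UBP1B, AT5TE28750 and RUBY (0.48, adjusted permutation p = 0.0916). The exact permutation test of RUBY gave a two-sided p = 0.000331 (adjusted p = 0.00116), that of the pA share p = 1.32e-05, the smallest possible (adjusted p = 6.17e-05), and that of the full-length ratio an adjusted p = 0.00225. The mutant libraries carry their own numbers, so a batch cannot be told apart from genotype. Against the Col-0 libraries of the first and of the second set RUBY differed by 0.92 and 0.58, the pA share by -19.9 and -19.7 points and the full-length ratio by 3.49 and 5.36; 16 of the 29 targets passed against both (12 higher, 4 lower), while SADHU1-1 (-0.35), AT2G02210 (0.00) and AGL20 (0.02) lost or turned their change against the first, where AT4G07967 (-0.25) and AT1G62920 (-0.17) did not pass either. Of the unmethylated transposable element class 5 rose and 2 fell of 7 tested, and of the list of transposable elements 5 rose and 5 fell of 16 (10 adjusted over the list alone, camera adjusted p = 0.931). The list holds elements listed under genes, and overlapping targets share reads, so its calls are not of independent elements. The 8 mutant leaves come from 2 lines, and with 1 value per line and group 6 targets passed. RUBY (0.77), the pA share (-19.8 points) and the full-length ratio (4.88) then kept their direction but did not pass.

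**Figure D3:**
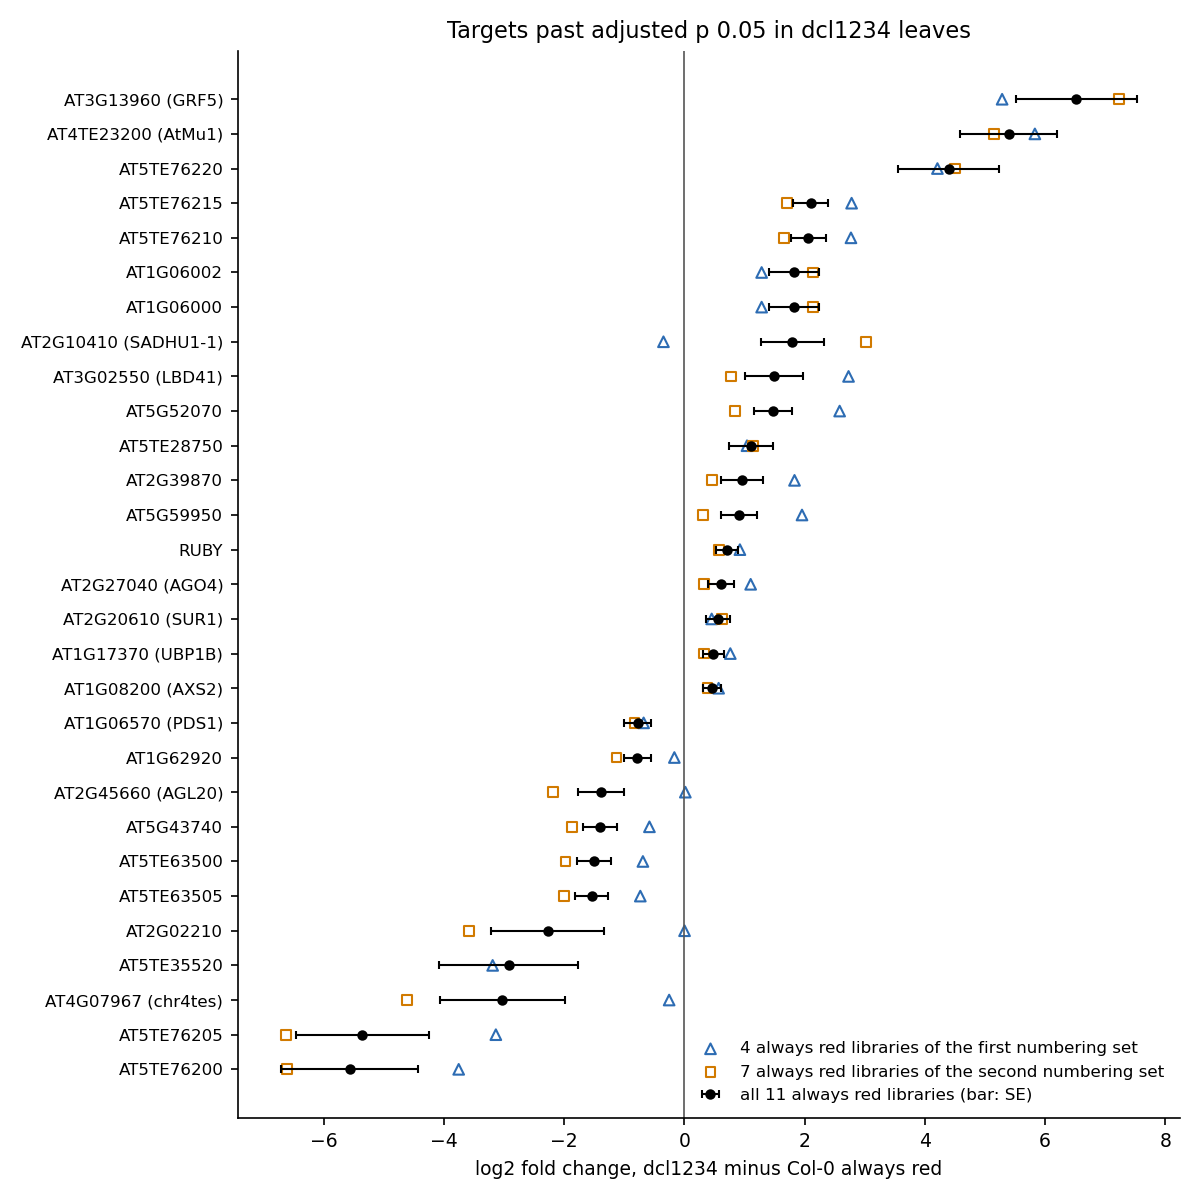
Log2 fold change of dcl1234 over Col-0 in always red 35S leaves for the 29 targets that passed, with black points and SE bars from all 11 Col-0 libraries, triangles against 4 of the first numbering set and squares against 7 of the second. GRF5 is highest at 6.52 and AT5TE76200 lowest at -5.57, and SADHU1-1 lies on both sides of 0.

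Under the ZmUBQ promoter RUBY was lower in fully green than in fully red leaves, at 37948 ± 10173 against 179432 ± 50892 (SD, n = 9 and 9), a log2 fold change of -2.24, with no overlap. Reads marked pA fell by 2.95 on the log2 scale and the others by 1.31, and the pA share was 49.3% ± 18.5 against 74.8% ± 4.33. TAS3 had a change of 0.85, AGO1 of -0.22, DCL4 of 0.28, AT2G40030 of 0.57, AT5TE63500 of 0.31 and GUS of 2.81, none of which passed over all targets (TAS3 unadjusted limma p = 0.0188). The exact permutation p of RUBY was 4.11e-05, the smallest possible (two-sided, adjusted p = 0.000192), and the pA share had an adjusted permutation p = 0.00216. By limma RUBY alone passed of 51 targets (SE 0.17, adjusted p = 3.93e-10; 9 at an unadjusted p below 0.05), with a shift of the others of 0.12 and a centred RUBY change of -2.30. The full-length ratio differed by -0.82 (adjusted permutation p = 0.396), on full-length signals of 2.34 ± 3.47 and 27.8 ± 21.1.

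Fully red ZmUBQ leaves had more RUBY than always red ones, at 179432 ± 50892 against 108603 ± 34246 (SD, n = 9 and 4), a log2 fold change of 0.73, with a pA share of 74.8% ± 4.33 against 77.2% ± 1.74, which did not pass. AGO1 (0.44), TAS3 (-0.74), DCL4 (-0.18), AT2G40030 (-0.81), AT5TE63500 (0.15) and GUS (-1.77) did not pass. The exact permutation p of RUBY was 0.00839 (two-sided, adjusted p = 0.0196), and the call ended with centring (0.67, adjusted permutation p = 0.156) and without always red leaf MK054_1 (0.58) or MK054_2 (0.63). By limma 0 of 57 targets passed, RUBY included (7 at an unadjusted p below 0.05).

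The change from fully red to fully green was set side by side for the 2 promoters. RUBY differed by 0.68 between them (35S minus ZmUBQ; limma SE 0.35, p = 0.0591, adjusted p = 0.934 over all targets), and no target passed in limma. Centred, the difference was 0.34. The numbering sets bear on it: with leaves matched by line and replicate number it was 1.18 for 35S leaves of the first set and 0.27 for those of the second, which did not pass (exact permutation p = 0.0874).

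**Figure D4:**
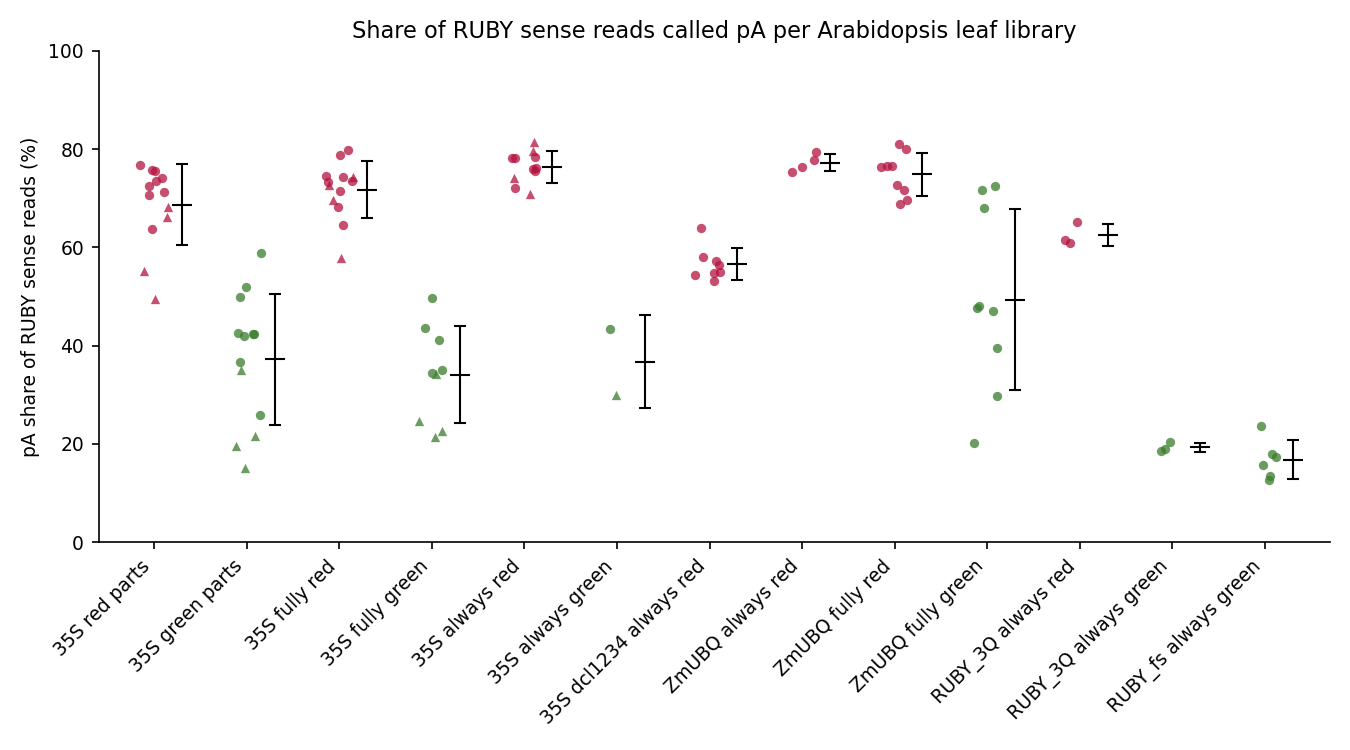
Percent of RUBY sense reads marked pA in each leaf library by construct and colour, with triangles for libraries of the first numbering set, circles for the others and a black bar for the mean ± SD. Red groups with 3 or more libraries average 56.6% to 77.2% and green groups 16.7% to 49.3%.

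With RUBY_3Q, always green leaves held much RUBY RNA, at 639227 ± 192222 against 389168 ± 94711 in always red leaves (SD, n = 3 and 3; log2 difference 0.70). Their pA share was 19.3% ± 0.977 against 62.5% ± 2.27, and full-length RUBY reads had a signal of 4.29 ± 3.85 against 443 ± 280.1 (log2 difference -6.53; full-length ratio -7.22). TAS3 had a change of -1.14, AGO1 of -0.49, DCL4 of -0.83, AT2G40030 of -3.28 and AT5TE63500 of 0.51, none of which passed over all targets. The exact permutation p of the pA share and of the ratio was 0.1, the smallest that 3 against 3 allows, so neither can pass. By limma 0 of 46 targets passed (4 at an unadjusted p below 0.05), with a shift of -0.75. The list of transposable elements (5 tested, median 0.54) was higher as a set (camera, adjusted p = 0.0168), with adjusted p = 0.755 with an estimated correlation.

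Always green leaves with RUBY_fs had a RUBY signal of 611544 ± 204301 against 389168 ± 94711 in RUBY_3Q always red leaves (SD, n = 6 and 3; log2 difference 0.59, adjusted permutation p = 0.233), but reads not marked pA rose by 1.74 and the pA share was 16.7% ± 3.95 against 62.5% ± 2.27. Full-length RUBY reads had a signal of 4.77 ± 5.17 (log2 difference -6.54; full-length ratio -7.13). LBD41, a transcription factor gene, fell to 1081 ± 602 from 6536 ± 2343 (log2 fold change -2.71, SE 0.60). TAS3 (0.42), AGO1 (-0.41), DCL4 (-0.49), AT2G40030 (-1.79) and AT5TE63500 (0.15) did not pass. The exact permutation p of the pA share was 0.0119, the smallest possible (two-sided, adjusted p = 0.0299), and the full-length ratio had an adjusted permutation p = 0.0453. By limma LBD41 alone passed of 52 targets (adjusted p = 0.011; 4 at an unadjusted p below 0.05), and 0 passed without always red leaf SL2621_4 or SL2621_5; the others were shifted by -0.60, and with centring 4 rose and 1 fell. The RUBY_fs leaves are of line SL2622 and the RUBY_3Q leaves of line SL2621, so construct cannot be told apart from line here or between their always green leaves. The list of transposable elements (8 tested, median 2.54) was higher as a set (camera, adjusted p = 1.95e-05, and adjusted p = 0.0205 with an estimated correlation), though no member passed alone. AT5TE76205, AT5TE76220, AT4TE23185, AT5TE85500 and AT4TE20085 were at 0 in all 3 always red libraries and were tested only through the green ones. With 6 green against 3 red libraries the filter favours such members, so the set test cannot decide on a rise.

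Between the always green leaves of RUBY_fs and RUBY_3Q, RUBY differed by -0.11, the pA share by -2.52 points and the full-length ratio by 0.09, none of which passed by exact permutation test (6 against 3). TAS3 was at 23896 ± 14617 in RUBY_fs against 7699 ± 3388 in RUBY_3Q (log2 difference 1.56), which did not pass over all targets (limma adjusted p = 0.221, unadjusted p = 0.00417). With centring it did (1.43), as did LBD41 (-2.06), both with limma adjusted p = 0.0195. AGO1 (0.08), DCL4 (0.34), AT2G40030 (1.49) and AT5TE63500 (-0.36) did not pass. By limma 0 of 53 targets passed (3 at an unadjusted p below 0.05).

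In lettuce, green leaves held little RUBY RNA. Under the 35S promoter RUBY was at 60.1 ± 41.3 in always green and 56779.6 ± 27416 in always red leaves (SD, n = 3 and 3; log2 fold change -9.98), and at 2369 ± 1189 in fully green and 74164 ± 50443 in fully red leaves (n = 3 and 3; -4.90). Under ubiquitin promoters it was at 119 ± 173 in always green and 10533 ± 3007 in always red leaves (n = 6 and 6; -7.57), and at 691 ± 174 in green and 4761 ± 1001 in red parts (n = 4 and 4; -2.80). In each of the 4 comparisons every green library lay below every red one. No lettuce line gave always green and also always red leaves, so in those comparisons colour cannot be told apart from line. On the labels the ubiquitin always green leaves carry the Arabidopsis promoter, and always red leaves of lines Ls951 and Ls998 the lettuce one. UBP1B, an RNA-binding protein gene of Arabidopsis, was at 169 ± 140.1 in fully green and 38.8 ± 42.9 in fully red leaves (log2 2.29), or 13 to 70 against 3 to 24 reads. The groups overlap, and the highest value, 326, is in green library Ls608_1, which holds reads of 26 Arabidopsis targets; without it the call ended (1.65, limma adjusted p = 0.195). The RUBY signal of Ls608_1 is in the fully green mean, and whether it shares a source with those reads was not tested. The AGL20 target was listed at 0 in all 4 green parts, with a mean of 15.8 ± 10.8 in red parts, about 1 to 6 reads per library. The pA share of RUBY did not pass in any of the 4, and with 3 against 3 libraries it could not. It was 71.8% (67.1% to 75.6%) against 59.1% ± 10.5 in fully green and fully red leaves and 22.3% ± 2.41 against 28.8% ± 8.94 in green and red parts.

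For the 35S lettuce comparisons the exact permutation p of RUBY was 0.1, the smallest possible, and limma gave adjusted p = 2.23e-07 (1 of 4 tested targets passed) and 0.000415 (2 of 3). For the ubiquitin promoters the exact permutation p was 0.00216 for whole leaves (adjusted p = 0.00606) and 0.0286 for parts (adjusted p = 0.0571), both the smallest possible, with limma adjusted p = 3.05e-06 (1 of 4 passed) and 7.5e-07 (2 of 4). The tables give few targets for a scale to rest on: the other targets were shifted by -0.34, 1.46, 0.35 and -0.31 in the order above, and centred RUBY changes were -9.64, -6.36 and -8.02 in the first 3 of them, and green parts kept their call. In fully green against fully red leaves 0 targets passed, RUBY included, without green library Ls608_2 or without any 1 of the 3 red libraries, and 1 passed without green library Ls608_1.

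Over the 12 Arabidopsis comparisons, fitted without the numbering set, the silencing machinery list had up to 8 tested members; 1 call was a rise and 1 a fall, both of AGO4, and 2 passed adjusted over the list alone. TAS3, the tested tasiRNA precursor, passed in 0 comparisons by limma over all targets; it is the 1 tested member of its list, and its unadjusted p was below 0.05 in 5 of the 12. Of 24 set tests with camera 3 passed, each for transposable elements, and 1 did with an estimated correlation; the third is always green against always red 35S leaves (24 tested, median -0.92, mean -0.38, higher relative to the other targets; adjusted p = 0.0168, and adjusted p = 0.49 with an estimated correlation).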

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

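The comparison of the 2 promoters was set in advance for RUBY as a whole; its tests on reads marked pA or not, with centring and by numbering set were chosen only after the results were seen.

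Libraries under no comparison gave RUBY values of their own, each a single leaf unless stated. In leaves of primary transformants (T1, 35S) RUBY had a signal of 728103 in always green, 586984 in always red, 179567 in fully green and 523347 in fully red, with pA shares of 12.9%, 53.2%, 20.9% and 50.2%. With RUBY_3Q the mean pA share was 66.7% in 2 fully red leaves and 27.3% in 2 fully green leaves, and in 2 fully red lettuce leaves with a ubiquitin promoter it was 20.3%. The leaf titled Col-0 Green, whose label names the 35S RUBY construct, had a RUBY signal of 295 and a GUS signal of 609741; whether this leaf carries RUBY is not settled by the labels. Among reads collapsed by molecular identifier NosTerm had a signal of 534 in the poliv polv inflorescence library, against 110.0 ± 187 in Col-0 (SD, n = 3, highest 326). Among all reads it was at 8365, against 470, 9.38 and 1.70 in the Col-0 libraries.

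The change of RUBY from fully red to fully green leaves differed between promoters by 0.675 on the log2 scale when leaves were matched by line and replicate number (35S -1.57 ± 0.865, ZmUBQ -2.24 ± 0.235, n = 9 and 9; exact permutation p = 0.00909, adjusted p = 0.0455 over 5 measures). Among reads not marked pA the difference was 0.894 (exact permutation p = 0.0218, adjusted p = 0.0545). The labels do not say that leaves of the same number share a plant, and not every library was closest to its own number. The limma test of the same difference, on unmatched leaves, had p = 0.0591, and with libraries centred on their median the difference was 0.337 (limma p = 0.475). With the 35S leaves of the first numbering set alone it was 1.18 (n = 4, exact permutation p = 0.0042), and with those of the second 0.270 (n = 5, exact permutation p = 0.0874), so a difference between promoters is not shown apart from the numbering sets.

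The RUBY level, pA share and full-length ratio were looked at in 10 groups of 4 to 10 libraries, 26 sets of values in all, for a library far from the rest. There were 5, in 4 of the groups, where chance gives about 1 in 20 groups for a single measure; the measures of a group are not independent, so the 5 were not set against chance. These were a RUBY level of 17.95 (log2) in always green RUBY_fs leaf SL2622_12, whose nearest neighbour was at 19.08, and of 12.61 in lettuce red part Ls889_4, with the nearest at 12.09. In dcl1234 leaf MK073_3 the pA share was 63.8%, with the nearest at 58.0%, and the full-length ratio -12.11, with the nearest at -9.55. In always green lettuce leaf Ls700_1 the pA share was 100%, with the nearest at 33.3%, on a RUBY signal of 5.14, the smallest value above 0 in its table.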

How the results depend on the processing

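The alternatives were set before the data were examined, except those on numbering sets (with centring too), the pA share and reads marked pA or not, and blocks, line means and left-out libraries for the full-length ratio, which were chosen after seeing the data. Of 174 alternative counts of targets 134 stayed within 1.5 times the reported count and 40 moved. For RUBY 98 of 116 alternatives kept direction and side of the threshold, for the full-length ratio 40 of 55, and for the pA share 60 of 73, with no reversal. For the single targets named and reads marked pA or not, 593 of 676 did, 72 lost and 4 gained a call, and 7 reversed. Where no cause is named the cause was not tested.

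Centring moved the count of targets to 51 in ddm1, where it took 1.94 from every log2 change, 1 in 35S fully red against always red, 1 in 35S always green against always red, 5 in RUBY_fs against RUBY_3Q always red and 2 against RUBY_3Q always green. The table of full-length reads collapsed by molecular identifier gave 2 in polv, 3 in 35S fully green against fully red, 3 in RUBY_3Q always green against always red, and 7 and 1 in RUBY_fs against RUBY_3Q always red and always green; the full-length table gave 2 in polv. Without trend and with robust moderation 1 target passed in 35S always green against always red and 0 in RUBY_fs against RUBY_3Q always red. In 35S always green against always red pseudocounts of 0.1 and 10 gave 5 and 6, the set as a term 28 (25 lower), and the set with centring 2 (0 lower). In lettuce 35S fully green against fully red a pseudocount of 10, no filter and the replicate block, with numbers from the sample titles, gave 1 each. The block gave 8 and the set as a term 7 in 35S fully green against fully red. Line means, with fewer values, gave 6 in dcl1234 and 2 in ZmUBQ fully green against fully red. Within the first and second numbering set, with fewer libraries, the counts were 0 and 2 for parts, 0 and 4 for fully green against fully red, and 2 and 2 for fully red against always red. With an estimated correlation 1 list passed. Leaving out single libraries gave 13 to 43 targets in polv (43 without Col-0 replicate 2). In 35S always green against always red it leaves 1 green leaf, so no count is given. It gave 0 to 3 in RUBY_3Q always green against always red (3 without SL2621_8). In RUBY_fs it gave 0 to 1 against RUBY_3Q always red (0 without SL2621_4 or SL2621_5) and against always green (1 without SL2621_8). In lettuce 35S fully green against fully red it gave 0 to 2. There 0 passed without fully green Ls608_2 or fully red Ls608_1, Ls608_2 or Ls745_3, and 1 without fully green Ls608_1.

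RUBY lost its call within the first set (-1.08 in parts and -1.06 in fully green against fully red, 4 against 4), in dcl1234 with centring (0.48) and line means (0.77), and with line means, where values are few, in ZmUBQ fully green (-2.27) and fully red against always red (0.72) and lettuce ubiquitin always green (-7.48). In ZmUBQ fully red against always red it lost it also with centring (0.67), on the collapsed full-length table (2.11) and among left-out libraries (0.58 to 0.91). On that table RUBY reversed to -3.63, -6.53 and -6.54 in always green against always red of 35S, of RUBY_3Q and of RUBY_fs against RUBY_3Q. Left-out libraries gave -0.57 to 0.61 in 35S always green against always red and -0.37 to 0.0800 in RUBY_fs against RUBY_3Q always green (reversed without MK017_2 and SL2621_7). The promoter difference passed by permutation of matched leaves (0.675) and with 35S leaves of the first numbering set (1.18), and did not with those of the second (0.27) or with centring (0.34).

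The full-length ratio of green against red parts lost its call with a pseudocount of 10 (-1.06), the block (-2.01), line means (-1.99) and within sets (-3.98 and -1.13); fully green against fully red gained one minus the median of other targets (-3.09) and with the block (-3.23), and 35S always green minus others too (-3.59). It lost the call with line means in dcl1234 (4.88), and among left-out libraries in RUBY_fs against RUBY_3Q always red (-7.40 to -6.69). It reversed to -0.51 in 35S fully red against always red within the first set and to 0.83 in ZmUBQ fully green with a pseudocount of 10, and ranged from -0.80 to 0.93 in RUBY_fs against RUBY_3Q always green (-0.80 without SL2621_7). The pA share lost its call within the first set (-37.0 in parts, -42.9 in fully green), with line means in dcl1234 (-19.8) and ZmUBQ fully green (-25.0), and among left-out libraries, where the smallest possible p rises, in 35S always green (-46.4 to -32.9) and RUBY_fs against RUBY_3Q always red (-46.5 to -44.4). In 35S fully red against always red it lost it minus other targets (-3.40), with line means (-4.20) and within sets (-7.88 and -3.14).

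Reads not marked pA reversed in fully green within the first set (0.20) and without SL2621_7 (0.11) or SL2621_8 (0.0206) in RUBY_fs against RUBY_3Q always green, where values ranged from -0.33 to 0.11. AGO4 in 35S always green turned to 0.0323 on the collapsed full-length table, and against the first set SADHU1-1 turned to -0.35, AT2G02210 to 0.00438 and AGL20 to 0.0174 in dcl1234. No block was used in the report, as in no comparison was every library closest to its own number. After removing group means, the correlation across targets of a pair passed 0.1 in 2 of 3 pairs in ddm1 and 1 of 3 in polv. It did in 8 of 13 in parts, and in 5 of 9 in 35S and 1 of 9 in ZmUBQ fully green against fully red. In lettuce it did in 1 of 3 in each 35S comparison and 2 of 4 in parts. Its median was 0.21 in 35S parts, against -0.006 for libraries of different numbers, and 0.21 against -0.03 in 35S fully green against fully red. In ddm1 it was higher too, and in polv, ZmUBQ and lettuce lower. So a pairing of 35S leaves is not excluded, and tests without a block take such leaves as independent. Depth limits lettuce most, where a library's sum is a median of 832 reads, by the worth of 1 read inferred from its low values.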

Other observations

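All tests of explanations in this part were chosen only after the results were seen.

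The few reads of methylated transposable elements in Col-0 inflorescences had another form than those in ddm1. Their summed signal was 400.4 ± 356 in Col-0 (SD, n = 3), with 5.57% ± 3.20 marked pA and 38.8% ± 5.01 antisense. In ddm1 it was 19852 ± 3025 (n = 3), with 49.7% ± 3.60 marked pA and 22.0% ± 6.52 antisense. In polv it was 13.9 ± 3.40 (n = 3). Protein-coding targets had pA shares of 59.4% ± 4.72 in Col-0 and 64.5% ± 2.15 in ddm1, with 1.58% ± 0.424 and 1.97% ± 0.410 antisense.

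The lower pA share of RUBY in green 35S leaves might come from a loss of pA reads over the whole library, but the share of the other targets was higher by 3.29 points in fully green than in fully red leaves, and RUBY minus the other targets differed by -41.0 points (permutation adjusted p = 2.81e-05). The numbering sets as a cause are argued against by the difference of fully green from fully red leaves within sets. It was -32.4 points in the set where it was nearest to 0. What remains open, as a hypothesis with no test here, is RUBY RNA made or trimmed without a poly(A) tail in green tissue.

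The fall of methylated transposable element reads in polv could reflect reads carried over from ddm1 libraries into Col-0; the pA share of 5.57% in Col-0 (highest 8.37%), against 46.4% in the lowest ddm1 library, argues against it. Signal taken up by the NosTerm target in polv is argued against as well, since the median log2 change of the 14 tested targets was -3.48 with the share of construct targets removed, with the lowest Col-0 library at 173 and the highest polv library at 22.9. A candidate explanation is that these reads depend on Pol V, and the double mutant library, with a class sum of 18.2 against 189 in the lowest Col-0 library, goes with it. That is a hypothesis from 1 library. Genomic DNA in the libraries was not tested.

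Lettuce library Ls608_1 (35S, fully green) had 29 targets above 0, against 3 to 7 in the other 35 lettuce libraries, among them 26 Arabidopsis targets with a summed signal of 6691. Reads from Arabidopsis libraries are a candidate source: the values followed the mean of the Arabidopsis 35S leaves with a rank correlation of 0.767 across targets, which are not independent replicates. Lettuce transcripts held by the probes are argued against as the source of all 26: the 10 lettuce libraries with at least as many reads, by the worth of 1 read inferred for each, held 2 to 4 of them. These 10 are red. Fully green library Ls608_2, with fewer reads, held 4 of the 23 targets that would have at least 3 reads there at the same signal. For the 7 targets above 0 in at least 2 other lettuce libraries the sources cannot be told apart, since those libraries show such reads too. No biological explanation was tested.

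Other splits of the same libraries into groups of the same sizes were tested for the number of targets that pass. Chance can be excluded for dcl1234 against Col-0 (29 targets, 1 of 100 splits gave as many, the real one, highest other 1). It can be excluded too for lettuce ubiquitin green against red parts (2 targets, 1 of 35, highest other 1). The last rests on AGL20 as the second target, at 1 to 6 reads in red parts, as RUBY alone would make a count that other splits reach. This holds for chance among exchangeable leaves and does not cover differences between lines or, in lettuce, between promoter labels. The dcl1234 leaves, with numbers of their own, and the lettuce always green leaves come from 2 lines each. With line means 6 targets passed in dcl1234. In lettuce RUBY lost its call (-7.48), where the lines are too few for a permutation test to pass. Counts of targets do not exclude chance for 35S green against red parts (1 target; 6 of 100; highest other 30), 35S fully green against fully red (1; 5 of 100; 33) and ZmUBQ fully green against fully red (1; 9 of 100; 5). In these 3 the target is RUBY, for which its own permutation test excludes chance among exchangeable leaves (p = 1e-05, 4.02e-06 and 4.11e-05). Within the second numbering set the exact permutation p was 4.11e-05 for parts and 0.0005 for fully green against fully red. These tests shuffle leaves without regard to line. With line means RUBY kept its call in the 35S comparisons and lost it in ZmUBQ (-2.27), where values are few. For RUBY_fs always green against RUBY_3Q always red (1 target, LBD41; 8 of 84; 23) chance cannot be excluded. Where 0 targets passed every split gives as many, so the splits decide nothing for 35S fully red against always red (100 of 100; highest other 10), ZmUBQ fully red against always red (100 of 100; 11) and RUBY_fs against RUBY_3Q always green (84 of 84; 19). Splits with 30 or 33 targets point to a structure of the 35S libraries, and the splits took no account of the numbering sets, between which 40 of 57 and 36 of 60 targets differed. With 10 splits no share under 0.05 can be had for ddm1 (17 targets; highest other 1), polv (16; 0), RUBY_3Q always green against always red (0; 2), lettuce 35S fully green against fully red (2; 2) and always green against always red (1; 1).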
